A study of Mus musculus with 4 samples.

How the data were processed

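Single-cell RNA-seq libraries were made from the small intestine of 4 C57B/6 wild-type mice, 1 library per mouse. Per the labels, the mice were fed the AIN76A purified diet from 3 weeks of age, and 2 were 24 months old (old) and 2 were 3 months old (young). Per the labels, EpCAM-positive, CD45-negative cells were collected by flow sorting, about 10000 cells per mouse were loaded on a 10x Genomics Chromium Chip B with the 3' kit, and the libraries were sequenced on a NovaSeq X Plus. The deposited values are UMI counts per gene and cell barcode, with barcodes already called as cells and no further scaling. Cell Ranger 8.0.1 and bcl2fastq with the mm10 mouse genome build are named in the submitters' processing notes. The gene annotation release and whether intron reads were counted are not given in the sources used here. Replicate numbers follow the order of the samples in the series and pair no old mouse with a young mouse.

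All tables held the same 32285 genes. Gene positions and processed pseudogenes were taken from GENCODE M21 on mm10, where 32235 gene identifiers matched. Among them, 963 genes hold a processed pseudogene on their own strand and 1353 hold one on the opposite strand alone. A barcode was kept as a cell with at least 500 detected genes, at least 1000 UMIs and at most 25% of UMIs from mitochondrial genes. Doublets were then removed with Scrublet as run in scanpy 1.11.5 (expected rate 0.08). The libraries held 11569 and 10177 barcodes (old replicates 1 and 2) and 7011 and 10465 barcodes (young replicates 1 and 2), and 9810, 8219, 4721 and 7643 cells were kept.

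Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes were reduced to 30 principal components, leaving out mitochondrial, ribosomal protein and sex-linked genes. A shared-neighbour graph of 20 neighbours was clustered with the Leiden method (leidenalg 0.10.2) at resolution 1, all libraries together and without batch correction. Each cluster was named after the class whose fixed markers lay highest above their mean over clusters, on log2 CPM with a pseudocount of 10 CPM. A name needed a score of at least 0.5 and at least 3 markers detected in 5% of the cluster's cells. A cluster also stayed unnamed if its median UMIs per cell lay below 1/3 of the library median and its 10 leading genes held no marker of the class. Clusters without such a name, and clusters named after leukocytes, were left out of the comparisons. Class names are written with "like" because they rest on transcripts alone.

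Counts were summed per library and class, and CPM values in the text are taken over these sums with TMM scaling. Old and young sums were compared with edgeR 4.0.16 (R 4.3.3), with filterByExpr, TMM scaling and the quasi-likelihood test. The test covered all epithelial cells together and each class with at least 50 cells in every library, which left out Paneth-like cells. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are old minus young. Their standard error (SE) is the size of the difference divided by the square root of the F statistic of the quasi-likelihood test. It therefore restates the p-value and is no separate estimate of the spread between mice. It is unreliable for genes with almost no UMIs in an age. Levels are means with SD over 2 mice per age. The difference between the age effects of stem-like and enterocyte-like cells was tested as an interaction, with the mouse as a block. A set of 36 gene lists and 16 marker lists was fixed before the data were examined. Lists with at least 4 tested members were compared with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Of 287 list tests, 109 passed at the preset correlation. The 81 that also had a median log2 difference of at least 0.3 in size were eligible for description, a bound chosen after the lists were seen. Of these 81, none passed camera with an estimated correlation, where the smallest adjusted p was 0.406, and 2 passed with fry.

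Shares of epithelial cells per class were given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error within a library only. Their age difference was tested with an exact two-sided permutation test over the 6 arrangements of the 4 mice, in which the smallest p is 0.333, with Benjamini-Hochberg adjustment over the classes. Genes are named by a rule fixed before the data were examined. It takes called genes with a mean of at least 10 CPM and both old libraries on the same side of both young libraries, up to 10 in each direction by size of change (5 in transit-amplifying-like, goblet-like, enteroendocrine-like and tuft-like cells). It adds up to 4 members per described list by smallest p, and Epcam, Ptprc, Lgr5, Bmi1, Cdkn1a, Cdkn2a, Xist and Ddx3y. Gene models without a symbol of their own were left out of that rule. A single gene among those taken by the rule was left out and is not reported here. For a gene with no UMI in an age, the fold is a lower bound against 3 counts over that age.

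The procedure was tested on simulated data made from the real means, with 100 genes changed 2-fold and 100 changed 4-fold, all at a mean of at least 10 CPM. It recovered 93 and 100 of them with 7 false calls in stem-like cells and 73 and 100 with 12 false calls in enterocyte-like cells. The corresponding values were 41 and 96 with 9 false calls in enteroendocrine-like cells, and 78 and 100 with 5 false calls in epithelial cells together. The simulated genes were independent and followed the dispersion trend, without a spread of their own or a shift shared within a library. These values therefore do not show how many changed genes would be recovered in the real data. Alternatives fixed before the data were examined were RLE size factors, library totals alone, no low-count filter, DESeq2 1.42.0, a mitochondrial limit of 10%, doublets kept, cluster resolution 2, each library clustered alone, at least 1000 genes per cell, class sums thinned to the lowest total, leaving out genes under 5% of their level in their highest class, and leaving out each library in turn. Leaving out genes that hold a processed pseudogene, lifting the mitochondrial limit, testing each enteroendocrine-like cluster alone and testing Paneth-like sums were chosen after the data were seen.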

Results

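The data are UMI counts of sorted small-intestine epithelial cells from 2 mice aged 24 months and 2 mice aged 3 months, and the comparison is between the ages. The libraries held 90063720 and 89404859 UMIs in old replicates 1 and 2, and 68218630 and 79566352 UMIs in young replicates 1 and 2. In the cells kept, the median was 7832.5 and 9568 UMIs per cell in the old libraries and 13357 and 9365 in the young libraries. The median mitochondrial share was 5.32% and 4.92% in the old libraries and 3.98% and 5.58% in the young libraries. More barcodes of the young libraries lay above the mitochondrial limit of 25% (27.5% and 21.8%) than of the old libraries (6.23% and 13.5%). The libraries also differed in sex-linked transcripts, for which the labels give no sex. Old replicate 1 held 6843 UMIs of the Y-linked gene Eif2s3y and 34 of Xist, the RNA that coats the inactive X chromosome. Old replicate 2 and young replicates 1 and 2 held 0 UMIs of Eif2s3y and 69379, 33621 and 56738 of Xist.

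Transit-amplifying-like cells, the dividing progenitors, made up 30.84% ± 1.46 (SD, n = 2) of epithelial cells in old mice and 19.62% ± 1.44 (n = 2) in young mice. The share was 29.8% (95% interval 28.9 to 30.7) and 31.9% (30.9 to 32.9) in the old libraries, and 18.6% (17.5 to 19.8) and 20.6% (19.7 to 21.6) in the young libraries. Paneth-like cells, the antimicrobial cells of the crypt base, made up 0.929% (0.748 to 1.14) and 1.09% (0.874 to 1.34) in the old libraries, 90 and 89 cells. In the young libraries they made up 0.150% (0.0603 to 0.309) and 0.346% (0.226 to 0.507), 7 and 26 cells. Goblet-like cells, which secrete mucus, were 7.62% ± 0.265 in old mice and 10.1% ± 0.668 in young mice. Tuft-like cells were 1.88% and 1.22% in the old libraries and 10.2% (9.34 to 11.1) and 1.89% in the young libraries, so that the difference of −4.49 points became −0.341 without young replicate 1. Both old values lay beyond both young values for these 4 classes, with p = 0.333 (exact permutation test, the smallest that 2 against 2 mice allow) and an adjusted p of 0.583. The old and young values of tuft-like cells overlapped at cluster resolution 2, with doublets kept and with no mitochondrial limit (exact permutation p = 0.667 each), and those of transit-amplifying-like cells with each library clustered alone (exact permutation p = 1; 25.6% and 21.4% in old, 16.2% and 26.1% in young libraries).

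Stem-like cells were 11.3% ± 1.80 of epithelial cells in old mice and 10.2% ± 2.19 in young mice (exact permutation p = 0.667). Enterocyte-like cells, the absorptive cells, were 44.9% ± 0.0919 and 49.3% ± 9.34 (exact permutation p = 1), and enteroendocrine-like cells, which secrete hormones, 2.78% ± 0.338 and 4.46% ± 2.18 (exact permutation p = 0.667). The enteroendocrine-like difference of −1.68 points was −0.137 without young replicate 1 and −3.22 without young replicate 2. The stem-like difference of 1.11 points was −0.169 without old replicate 1, −0.445 without young replicate 2 and 2.66 without young replicate 1. The enterocyte-like difference of −4.43 points was 2.18 without young replicate 2 and −11.0 without young replicate 1. No cluster was named M-cell-like. With each library clustered alone, the difference in transit-amplifying-like cells was 2.41 points and that in stem-like cells 6.95 points, and 81.8% of cells kept their class. At cluster resolution 2 the difference in Paneth-like cells was 2.61 points instead of 0.76. That value includes a cluster led by Car4 and Ces1f, with 156 and 123 cells in the old and 0 and 1 in the young libraries, which took the name without a Paneth marker among its 10 leading genes. With a mitochondrial limit of 10% the differences in stem-like and enterocyte-like cells were 0.412 and −1.88. The sort, the loading and the mitochondrial limit can set such shares. Among barcodes above that limit that met the other limits, 77.0 to 97.5% were nearest to enterocyte-like cells, and with them included the enterocyte-like difference was −9.63 points and the transit-amplifying-like difference 13.1 points.

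**Figure D1:**
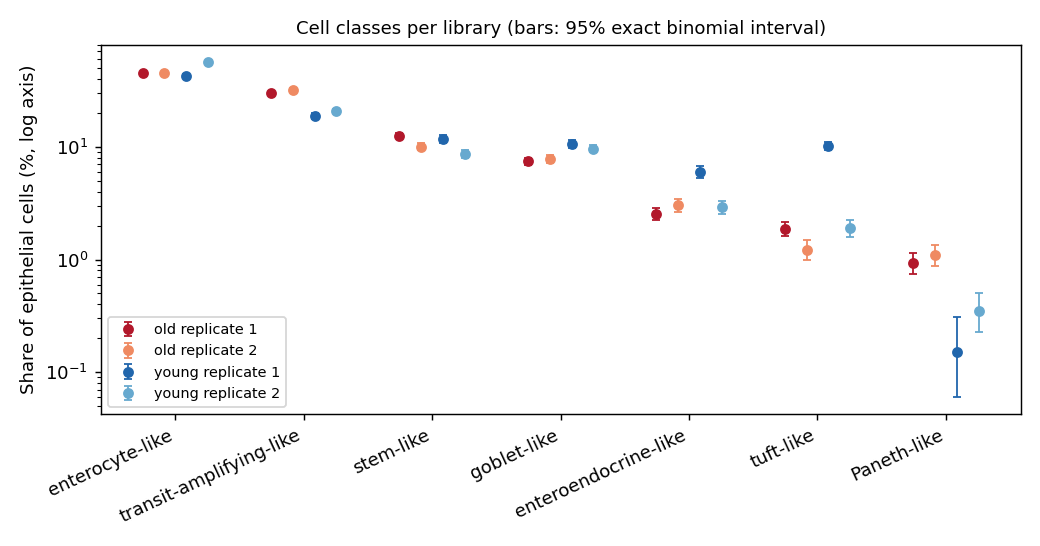
Share of epithelial cells in each class per library (log axis, percent; points are libraries, bars are 95% exact binomial intervals). Paneth-like cells lay at 0.929% and 1.09% in the old libraries and at 0.150% and 0.346% in the young libraries.

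With all epithelial cells summed, marker genes of several classes differed between the ages. Of 11 Paneth markers 9 were higher in old libraries (median log2 difference 1.67, camera adjusted p = 4.2e-05, adjusted p = 0.547 with an estimated correlation). All 12 transit-amplifying markers were higher (median 0.56, camera adjusted p = 1.2e-05, adjusted p = 0.547 with an estimated correlation), and all 35 proliferation genes (median 0.57, camera adjusted p = 7.2e-13, adjusted p = 0.526 with an estimated correlation), 21 of them when adjusted over the list alone. All 9 goblet markers were lower (median −0.58, camera adjusted p = 6.3e-06, adjusted p = 0.526 with an estimated correlation). All 12 tuft markers were lower (median −1.97, camera adjusted p = 2.0e-04, adjusted p = 0.686 with an estimated correlation), as were all 15 enteroendocrine markers (median −1.41, camera adjusted p = 3.3e-06, adjusted p = 0.581 with an estimated correlation). Without young replicate 1 these 2 medians were −0.51 and −0.68. Among single genes, Lyz1, the Paneth lysozyme, differed by 1.67 ± 0.17 (SE) on the log2 scale and Clca1, a goblet secretory protein, by −1.58 ± 0.15, each with an edgeR adjusted p of 0.0841. Cdkn1a, a cell cycle inhibitor, differed by −0.62 (adjusted p = 0.223), Epcam by −0.33 (adjusted p = 0.382) and Ptprc, which encodes CD45, by −3.00 (adjusted p = 0.288). Bmi1, a stem cell regulator, differed by −0.11 (adjusted p = 0.818) and Xist by −0.68 (adjusted p = 0.918), while Cdkn2a fell below the low-count filter.

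Interferon response genes were lower in old libraries in 35 of 37 members over all epithelial cells (median −0.96, camera adjusted p = 5.6e-14, adjusted p = 0.526 with an estimated correlation). Adjusted over the list alone, 16 were lower and 1 was higher. The median was −0.54 without young replicate 2. Isg15, an interferon-induced ubiquitin-like protein, differed by −1.64 ± 0.25 (adjusted p = 0.158), and Irf7, an interferon regulatory factor, by −1.19 (adjusted p = 0.107). MHC class I processing genes were lower in 15 of 16 (median −0.47, camera adjusted p = 1.3e-06, adjusted p = 0.526 with an estimated correlation), 8 of them when adjusted over the list alone, with H2-T23 at −1.09 (adjusted p = 0.107). Immediate early and dissociation stress genes were lower in 24 of 25 (median −1.05, camera adjusted p = 6.2e-08, adjusted p = 0.526 with an estimated correlation), with a median of −0.52 without young replicate 1. Fetal or regenerative genes were lower in 10 of 11 (median −1.17, camera adjusted p = 4.6e-06, adjusted p = 0.526 with an estimated correlation), and fry gave an adjusted p of 0.0264 for that list. Of the 81 lists eligible for description, 79 did not pass with fry (interferon response genes here at an adjusted p of 0.168). No single gene of the 15996 tested passed in edgeR, with 2327 at an unadjusted p under 0.05, and DESeq2 called 654 (247 higher, 407 lower). The edgeR count was 423 without old replicate 1, 227 without old replicate 2, 789 without young replicate 1 and 3310 without young replicate 2.

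In stem-like cells, the crypt-base cells marked by Lgr5 and Olfm4, genes of MHC class II antigen presentation were lower in old mice. Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, mm10 chromosome 18, 60803848 to 60812652), fell 5.98-fold from 22.5 ± 3.28 CPM in young mice to 3.72 ± 0.564 CPM in old mice (SD, n = 2 each; log2 −2.58 ± 0.22 SE, adjusted p = 0.00484). H2-Ab1, a class II beta chain, fell from 8.91 ± 0.316 to 1.14 ± 0.436 CPM (log2 −2.92 ± 0.34, adjusted p = 0.0112). All 4 tested MHC class II genes were lower (median −2.23, camera adjusted p = 4.8e-06, adjusted p = 0.556 with an estimated correlation, fry adjusted p = 0.0428, the other of the 2 lists that passed with fry), 2 of them called and 3 when adjusted over the list alone. At cluster resolution 2, which drew the class differently, Cd74 (log2 −1.19, adjusted p = 0.61) and H2-Ab1 (log2 −1.24, adjusted p = 0.635) were not called. The class then held 4969 UMIs of the immunoglobulin gene Igkc in old replicate 1, against 6 at the resolution used, at which these UMIs lay in enterocyte-like cells (4975), and Cd74 UMIs in that library went from 37 to 222. In the young libraries the stem-like sums held 0 UMIs of Igkc at either resolution. In enterocyte-like cells Cd74 was not called (log2 −0.62, adjusted p = 0.983), with 14.0 and 6.24 CPM in the old and 1.92 and 28.9 CPM in the young libraries. MHC class I processing genes were lower in 13 of 15 (median −0.32, camera adjusted p = 7.4e-04, adjusted p = 0.556 with an estimated correlation, fry adjusted p = 0.342) and did not pass without old replicate 1. Interferon response genes were lower in 17 of 23 (median −0.39, camera adjusted p = 0.0026, adjusted p = 0.556 with an estimated correlation, fry adjusted p = 0.331), with a median of −0.24 without old replicate 2, −0.11, not passing, without young replicate 2, and −0.21 at cluster resolution 2.

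Among other genes of stem-like cells, Cpm, which encodes carboxypeptidase M, fell 5.84-fold (log2 −2.55 ± 0.24, adjusted p = 0.00484) from 20.7 ± 3.90 to 3.55 ± 0.456 CPM. Adgrl2, an adhesion receptor, fell by 1.39 ± 0.20 on the log2 scale (adjusted p = 0.0375), Tifa by 0.81 ± 0.12 (adjusted p = 0.0428, with 0.176 without old replicate 2, 0.0529 at cluster resolution 2 and 0.0552 without genes holding a processed copy), and the nucleoside transporter gene Slc28a2 by 4.21 ± 0.45 (adjusted p = 0.00718). Ptpn6, which encodes the phosphatase SHP-1 (mm10 chromosome 6, 124720707 to 124738714), rose 3.93-fold from 9.04 ± 1.95 to 35.6 ± 5.01 CPM (log2 1.98 ± 0.20, adjusted p = 0.0057). Its level in stem-like cells was under 5% of that in its highest class, so that leaving out such genes removed it. Ctla4 (log2 1.86 ± 0.16) and Kalrn (log2 1.57 ± 0.15) were also called higher, but each holds a processed pseudogene on its own strand (Rpl18-ps1 and Gm49594), and Foxd2os (log2 1.91 ± 0.22) lies opposite another gene, so that these 3 are uncertain. Paneth markers were higher in 7 of 7 (median 2.23, camera adjusted p = 8.7e-07, adjusted p = 0.556 with an estimated correlation). Lyz1 rose from 7.85 ± 1.18 to 36.7 ± 8.68 CPM (log2 2.23 ± 0.22) and Itln1, a lectin, by 2.18 ± 0.23, while the alpha-defensins Defa17, Defa24, Defa30 and AY761184 were 2.73 to 3.23 higher on the log2 scale and belong to a family of near-identical genes. Paneth markers summed to 393 and 351 CPM in the stem-like cells of the old libraries, which had the larger share of Paneth-like cells, and to 47.4 and 72.6 CPM in those of the young libraries. At cluster resolution 2 Defa30 and Foxd2os were not called (adjusted p = 0.0526 and 0.0551).

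Lgr5, a receptor of Wnt-amplifying R-spondins, differed by −1.20 ± 0.23 in stem-like cells and was not called (adjusted p = 0.107), and the 10 tested stem markers were all lower, with a small median of −0.14 (camera adjusted p = 0.0149, adjusted p = 0.556 with an estimated correlation). Cdkn1a differed by −0.40 (adjusted p = 0.742), Bmi1 by 0.06 and Epcam by −0.32 (adjusted p = 0.568). Immediate early and dissociation stress genes were lower in 18 of 18 (median −0.44, camera adjusted p = 2.3e-04, adjusted p = 0.556 with an estimated correlation), with medians of −0.18 without young replicate 1 and −0.81 without young replicate 2. Of 11729 genes tested in stem-like cells, 30 were higher and 9 lower in old mice (edgeR). Library totals gave 52 and 26, a different balance of directions, and DESeq2 gave 42 and 21. The balance turned to more lower than higher genes without old replicate 1 (71 higher and 89 lower), without old replicate 2 (65 and 80), without young replicate 2 (324 and 523) and without the low-count filter (179 and 225).

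**Figure D2:**
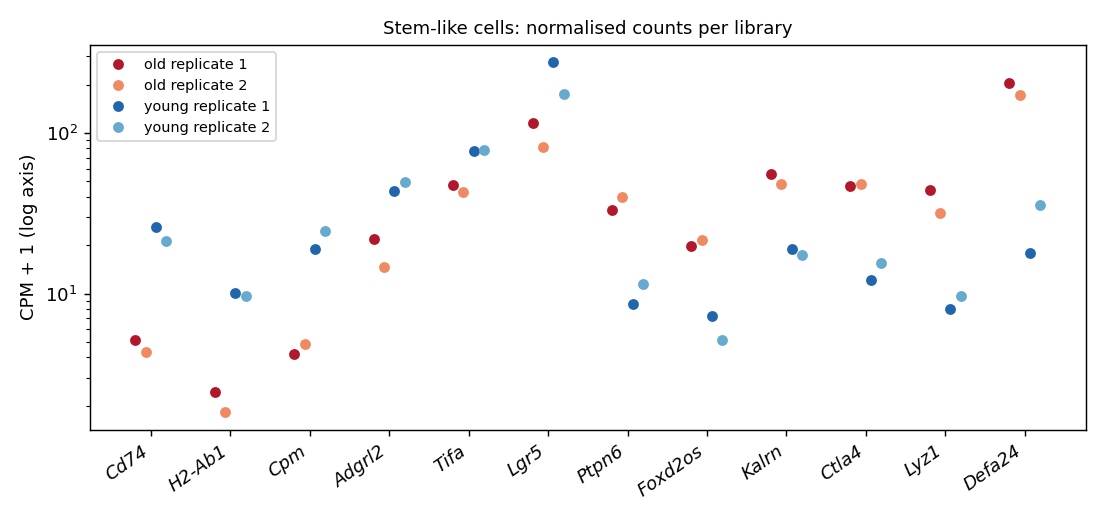
Normalised CPM plus 1 (log axis) of 12 genes in stem-like cells, 1 point per library. Cd74 had a mean of 3.72 in old and 22.5 in young mice, and Ptpn6 35.6 and 9.04.

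Whether stem-like and enterocyte-like cells differed in their age effect was tested directly, and no gene of 13852 passed in edgeR, with 583 at an unadjusted p under 0.05. The genes with the smallest p, chosen after their values were seen, were Ly6e and Phgdh. Ly6e, an interferon-inducible surface protein, differed by 0.81 in stem-like and by −0.29 in enterocyte-like cells (interaction 1.12 ± 0.15, adjusted p = 0.0874). Phgdh, an enzyme of serine synthesis, differed by −0.09 and 1.99 (interaction −2.04 ± 0.28, adjusted p = 0.0874). RLE size factors and library totals also gave 0, and the count was 20 without old replicate 1, 27 without old replicate 2, 394 without young replicate 1 and 209 without young replicate 2. DESeq2 was not used here for this test.

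In transit-amplifying-like cells, heat shock and immediate early genes were lower in old mice. Hspa1b, an inducible heat shock protein, fell from 14.9 ± 8.28 to 0.656 ± 0.161 CPM (log2 −4.49 ± 0.44, adjusted p = 0.008), and Hspa1a had 0 UMIs in old mice and 6.00 ± 3.22 CPM in young mice, at least 115-fold lower. Fos fell by 2.96 ± 0.47 on the log2 scale (adjusted p = 0.0434), and by 1.96 without young replicate 1. It was not called with library totals (adjusted p = 0.116), at cluster resolution 2 (0.0905), with a mitochondrial limit of 10% (0.0588) or without genes holding a processed copy (0.0578). Immediate early and dissociation stress genes were lower in 20 of 22 (median −0.62, camera adjusted p = 1.0e-08, adjusted p = 0.444 with an estimated correlation). Interferon response genes were lower in 27 of 29 (median −0.58, camera adjusted p = 1.9e-13, adjusted p = 0.444 with an estimated correlation). Isg15 was the called member (log2 −1.56 ± 0.25, adjusted p = 0.0463, and 0.081 without young replicate 1), and 13 members were lower and 1 higher when adjusted over the list alone. Isg15 was not called in the 4 settings that lost Fos (adjusted p = 0.134, 0.0837, 0.0572 and 0.06) or with thinned sums (0.0544). MHC class I processing genes were lower in 14 of 15 (median −0.46, camera adjusted p = 1.6e-05, adjusted p = 0.51 with an estimated correlation). MHC class II genes were lower in 4 of 4 (median −0.73, camera adjusted p = 0.0269, adjusted p = 0.601 with an estimated correlation), but did not pass without young replicate 2 (−0.21), with doublets kept (−0.62) or with a mitochondrial limit of 10% (−0.50), and the median was −1.43 without old replicate 2.

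Lists of absorptive-cell genes were also lower in old transit-amplifying-like cells. Villus tip genes (median −0.56, camera adjusted p = 3.1e-05) and proximal intestine genes (median −0.55, camera adjusted p = 0.0012) were lower, each with an adjusted p of 0.444 with an estimated correlation, and both medians were −0.35 with doublets kept. Enterocyte markers were lower in 15 of 17 (median −0.38, camera adjusted p = 1.9e-04, adjusted p = 0.51 with an estimated correlation), but did not pass with doublets kept (−0.14), without young replicate 1 (−0.19) or without genes under 5% of their highest class (−0.19). Slc28a2, in the villus tip list, fell by 4.03 ± 0.40 on the log2 scale (adjusted p = 0.008). Outside these lists Papss2, an enzyme of sulfate activation, fell by 1.27 ± 0.17 (adjusted p = 0.0268, and 0.0903 without old replicate 2) and Slc9a3, a sodium and proton exchanger gene, by 0.95 ± 0.15 (adjusted p = 0.0426). Slc13a1, a sulfate transporter gene, fell by 1.34 ± 0.20 (adjusted p = 0.0405), with the limit that it holds a processed pseudogene. Adgrl2 fell by 1.74 ± 0.20 (adjusted p = 0.0131) and AW112010 by 1.01 ± 0.16 (adjusted p = 0.0426). Slc9a3 was not called without old replicate 1 (adjusted p = 0.152) or old replicate 2 (0.115), nor AW112010 without old replicate 1 (0.173) or with thinned sums (0.0544), and neither was called without genes holding a processed copy (0.0578 each). At cluster resolution 2 Slc13a1, Slc9a3, Adgrl2 and AW112010 were not called (adjusted p = 0.099, 0.0645, 0.0614 and 0.0837), and with a mitochondrial limit of 10% Slc13a1, Slc9a3 and AW112010 were not called (0.0572, 0.0511 and 0.0511). With doublets kept Slc28a2, Papss2, Slc13a1 and Slc9a3 were not called, and with library totals Adgrl2, Papss2, Slc13a1, Slc9a3 and AW112010 were not called. The largest share of these cells in young replicate 1 (31.2%) came from a cluster led by Cdkn3 and Cdc20 that held 12.5% ± 1.78 of them in old mice.

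Ptpn6 rose by 1.68 ± 0.17 on the log2 scale in transit-amplifying-like cells (adjusted p = 0.00907), and Ctla4, with the limit named above, by 2.19 ± 0.19. Here too Ptpn6 lay under 5% of its level in its highest class. Paneth markers were higher in 9 of 10 (median 2.85, camera adjusted p = 4.5e-09, adjusted p = 0.444 with an estimated correlation). Lyz1 rose by 2.47 ± 0.38 (adjusted p = 0.0426) and Itln1 by 2.75 ± 0.43 (adjusted p = 0.0426), but without young replicate 1 neither was called (adjusted p = 0.0627 and 0.0764). Neither was called with doublets kept (log2 1.84 and 1.94, adjusted p = 0.295 and 0.301), at cluster resolution 2 (0.0992 and 0.099), with a mitochondrial limit of 10% (0.0511 each) or without genes holding a processed copy (0.0578 each), and DESeq2 did not call Lyz1. Ptpn6, Lyz1 and Itln1 were not called with library totals. Defa17 and Ftl1-ps1, a processed copy of a ferritin gene, were called higher and are uncertain because of near-identical genes, and Ftl1-ps1 was not called in 6 of the other settings, among them library totals (adjusted p = 0.124) and without young replicate 1 (0.0994). Of 13142 genes, 40 were higher and 23 lower, and library totals gave 13 and 4, a different balance. DESeq2 gave 81 and 74. The count of 63 became 176 without old replicate 1, 137 without old replicate 2 (67 higher, 70 lower) and 2218 without young replicate 2 (975 higher, 1243 lower).

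In enterocyte-like cells, all 34 interferon response genes were lower in old mice (median −0.89, camera adjusted p = 1.8e-18, adjusted p = 0.655 with an estimated correlation), 15 of them when adjusted over the list alone. The median was −0.38 without young replicate 2, which held 66 of the 96 cells of a cluster led by Ifit1, Isg15 and Rsad2. All 16 MHC class I processing genes were lower (median −0.51, camera adjusted p = 9.1e-09, adjusted p = 0.566 with an estimated correlation), 5 of them when adjusted over the list alone. All 23 immediate early and dissociation stress genes were lower (median −0.79, camera adjusted p = 3.0e-12, adjusted p = 0.566 with an estimated correlation), 8 of them when adjusted over the list alone, with a median of −0.48 without young replicate 1. At cluster resolution 2 a cluster of 62 enterocyte-like cells was led by Hspa1b, Hspa1a and Fos. It held 58 cells of young replicate 1, 4 of young replicate 2 and 0 of either old library. All 10 Paneth markers were higher (median 3.68, camera adjusted p = 4.5e-16, adjusted p = 0.566 with an estimated correlation), 9 of them when adjusted over the list alone, and 0 were called over all genes. Proliferation genes were higher in 28 of 35 (median 0.31, camera adjusted p = 2.1e-04, adjusted p = 0.566 with an estimated correlation). That list did not pass without old replicate 1 (median 0.24), without young replicate 2 (0.26) or without genes under 5% of their highest class (0.06).

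The main enterocyte-like cluster differed between libraries, with a cluster led by Gsdmc4 and Car4 in 35.6% ± 1.73 of these cells in old mice and 18.1% ± 7.0 in young mice. The largest was a cluster led by S100g and Slc40a1 in young replicate 1 (29.0%) and by Apoa4 and Lct in young replicate 2 (19.5%). The cluster led by Fabp6, a bile acid carrier of the distal small intestine, held 2.92% ± 0.17 in old and 7.30% ± 2.24 in young mice. Lipid uptake genes (median −0.12, camera adjusted p = 0.184) and nuclear OXPHOS genes (median −0.08, camera adjusted p = 0.098) did not pass. The 1 gene called of 13174 in edgeR was Fam83a, at 4.43 ± 0.104 CPM in old and 0.13 ± 0.0375 CPM in young mice (log2 5.10 ± 0.37, adjusted p = 0.0275), a gene below the 10 CPM minimum and chosen after its values were seen. There were 822 genes at an unadjusted p under 0.05, and DESeq2 called 111. The edgeR count was 128 without old replicate 1, 90 without old replicate 2, 297 without young replicate 1 and 406 without young replicate 2.

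In goblet-like cells, Ang4, an antimicrobial ribonuclease, fell from 243 ± 171 to 40.4 ± 2.79 CPM (log2 −2.59 ± 0.41, adjusted p = 0.0366), and by 1.60 without young replicate 1. DESeq2 did not call Ang4. The level of Ang4 in goblet-like cells was under 5% of that in its highest class, so that leaving out such genes removed it. Antimicrobial and barrier defence genes were lower in 15 of 17 (median −0.75, camera adjusted p = 1.6e-04, adjusted p = 0.556 with an estimated correlation), with a median of −0.32 that did not pass without young replicate 2. Hspa1b fell by 5.04 ± 0.83 on the log2 scale (adjusted p = 0.0423) and Junb, an immediate early transcription factor, by 1.5 ± 0.26 (adjusted p = 0.0491). All 22 immediate early and dissociation stress genes were lower (median −0.93, camera adjusted p = 1.9e-11, adjusted p = 0.556 with an estimated correlation), with a median of −0.56 without young replicate 1. Areg, an EGF receptor ligand, fell by 1.76 ± 0.28 (adjusted p = 0.039), in a list of fetal or regenerative genes in which 6 of 6 were lower (median −1.12, camera adjusted p = 1.3e-04, adjusted p = 0.556 with an estimated correlation; −0.61 without young replicate 2). MHC class I processing genes were lower in 14 of 15 (median −0.48, camera adjusted p = 2.3e-05, adjusted p = 0.556 with an estimated correlation), 9 of them when adjusted over the list alone.

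Hspa1b, Junb, Ang4 and Areg were not called in goblet-like cells with doublets kept (adjusted p = 0.0783, 0.0874, 0.0668 and 0.0597) or with library totals (0.0567, 0.0816, 0.0567 and 0.0568). Hspa1b and Junb were not called without genes holding a processed copy either (0.0548 and 0.0611), nor Junb with thinned sums (0.0546). Other genes that fell in these cells were Tceal8 (log2 −2.56 ± 0.35), Scd2, a fatty acid desaturase (log2 −2.27 ± 0.31), Pex5l (log2 −2.13 ± 0.28) and Cck (log2 −2.69 ± 0.43), the last not called with library totals (adjusted p = 0.0567). Cck too lay under 5% of its level in its highest class. Enteroendocrine markers, to which Cck belongs, were lower in 5 of 7 (median −1.15, camera adjusted p = 0.0232, adjusted p = 0.643 with an estimated correlation). That list did not pass with doublets kept (−0.09) or without young replicate 2 (−1.33), and its median was −1.93 without old replicate 2. Tuft markers were lower in 5 of 6 (median −0.82, camera adjusted p = 0.0406, adjusted p = 0.556 with an estimated correlation). They did not pass with doublets kept (−0.54), without young replicate 2 (−0.59), with thinned sums or with a mitochondrial limit of 10%, and the median was −2.82 without old replicate 1. P2rx7, an ATP-gated channel, rose by 1.55 ± 0.26 (adjusted p = 0.0432, 0.143 without old replicate 2, 0.0804 with doublets kept and 0.0549 without genes holding a processed copy). Wdr89 (log2 1.46 ± 0.14) and Rps27rt (log2 1.39 ± 0.17) were called higher, as were Ctla4 (log2 1.85 ± 0.20) and Kalrn (log2 1.75 ± 0.20). Ctla4 and Kalrn carry the limit named above, and Kalrn was not called with doublets kept (adjusted p = 0.0636). Wdr89, Rps27rt and Ctla4 belong to a set of 12 genes flagged below for possible misplaced reads. A cluster led by Zg16 and Clca1 held 7.13% ± 0.127 of goblet-like cells in old and 17.7% ± 6.75 in young mice. Of 11371 genes, 17 were higher and 21 lower, and library totals gave 20 and 9, with the median of all genes moved to 0.135. DESeq2 gave 24 and 42. The count of 38 became 293 without young replicate 1 and 380 without young replicate 2, and it was 0 without the low-count filter, with 1300 genes at an unadjusted p under 0.05.

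In enteroendocrine-like cells, several hormone genes were lower in old mice. Ghrl, which encodes ghrelin, fell from 16999 ± 15944 to 1728 ± 502 CPM (log2 −3.30 ± 0.57, adjusted p = 0.00964), and by 1.73 without young replicate 1. Cck, the cholecystokinin gene, fell from 21923 ± 8179 to 5658 ± 957 CPM (log2 −1.95 ± 0.36, adjusted p = 0.0142). Pyy, the peptide YY gene, fell by 2.39 ± 0.52 on the log2 scale (adjusted p = 0.0363; by 4.01 without old replicate 2) and Sst, the somatostatin gene, by 1.59 ± 0.37 (adjusted p = 0.0477, and 0.186 without old replicate 2). Gip differed by −1.17 ± 0.33 (adjusted p = 0.119) and Sct by −0.97, while the enterochromaffin genes Tac1 (0.35), Tph1 (0.32), Chga (−0.11) and Chgb (0.03) were not called. The list of enteroendocrine markers was lower in 11 of 15 (median −0.53, camera adjusted p = 5.0e-04, adjusted p = 0.411 with an estimated correlation), with a median of −0.80 without old replicate 2. A cluster led by Chga, Tph1 and Tac1 held 52.1% ± 1.86 of these cells in old and 36.2% ± 1.73 in young mice, and a cluster led by Gip, Cck and Ghrl held 22.5% ± 2.52 and 46.5% ± 4.43. DESeq2 did not call Ghrl, Pyy or Sst. Pyy was not called with doublets kept (adjusted p = 0.0879), and neither Pyy nor Sst was called with thinned sums (0.0567 and 0.0705), at cluster resolution 2 (0.0502 and 0.059) or without genes holding a processed copy (0.0505 and 0.057).

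Galnt13, a glycosyltransferase gene (mm10 chromosome 2, 54436317 to 55118309), fell 41.4-fold from 311 ± 68.8 to 7.36 ± 4.31 CPM (log2 −5.37 ± 0.34, adjusted p = 1.9e-06). Fam155a fell by 7.53 ± 0.49 on the log2 scale (adjusted p = 1.9e-06), Zfp804a by 5.78 ± 0.69, and Robo1, an axon guidance receptor, by 5.33 ± 0.79, which DESeq2 did not call (adjusted p = 0.0741). Without old replicate 1 the log2 differences of Galnt13, Fam155a, Zfp804a and Robo1 were −6.15, −11.03, −8.4 and −7.96. Without old replicate 2 they were −4.90, −6.66, −4.96 and −4.52. Nlgn1, a synaptic adhesion protein, had 0 UMIs in old mice and 39.9 ± 0.151 CPM in young mice, at least 31.1-fold lower. Peg3, an imprinted gene, fell from 282 to 22.9 CPM (log2 −3.64 ± 0.39, adjusted p = 2.3e-04) and Nrg1, the neuregulin 1 gene, from 1860 ± 505 to 250 ± 87.2 CPM (log2 −2.90 ± 0.31, adjusted p = 2.3e-04). Peg3 and Nrg1 were chosen after their values were seen. Within the Chga cluster alone, a test chosen after the data were seen, Fam155a fell by 6.75 ± 0.49, Nrg1 by 3.29 ± 0.32 and Peg3 by 3.31, while Pyy differed by 0.91 ± 0.42 (adjusted p = 0.304) and Cck by 0.33 (adjusted p = 0.808). Within the Gip cluster alone Galnt13 fell by 4.48 ± 0.38, Peg3 by 3.59, Pyy by 2.83 and Ghrl by 2.38 ± 0.61 (adjusted p = 0.0433), while Cck differed by −1.09 (adjusted p = 0.678), Sst by −0.67 and Gip by −0.31.

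**Figure D3:**
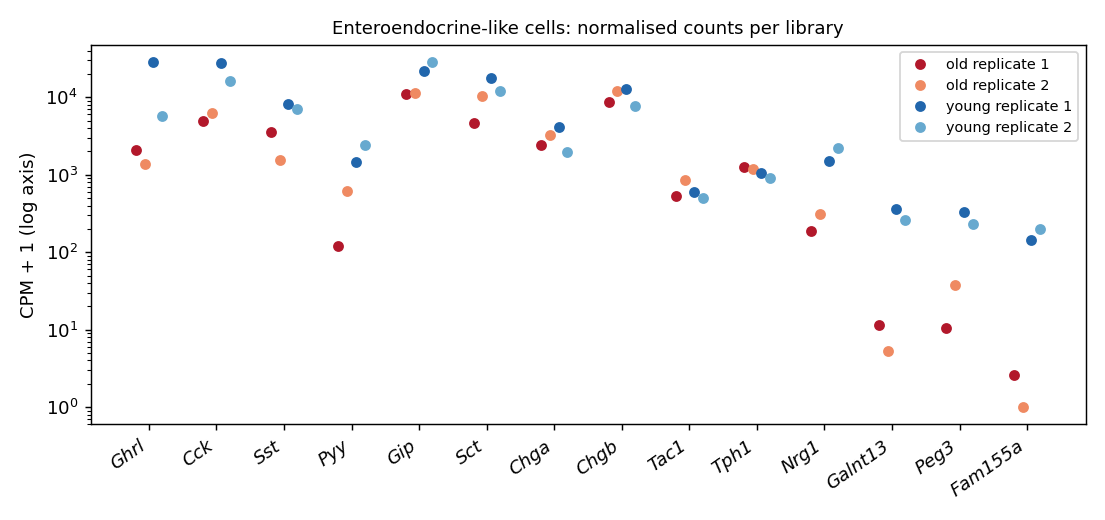
Normalised CPM plus 1 (log axis) of 14 genes in enteroendocrine-like cells, 1 point per library. Galnt13 had a mean of 7.36 in old and 311 in young mice, and Cck 5658 and 21923.

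Transcripts of absorptive cells were lower in old enteroendocrine-like cells too. Enterocyte markers were lower in 14 of 15 (median −1.16, camera adjusted p = 3.8e-10) and dietary lipid uptake genes in 20 of 21 (median −0.69, camera adjusted p = 8.0e-09), each with an adjusted p of 0.406 with an estimated correlation and 5 members called. Apoa1 (log2 −1.44 ± 0.25) and Apoc3 (log2 −1.47 ± 0.28), apolipoproteins of chylomicrons, fell, as did Rbp2 (log2 −1.60 ± 0.24), the glucose transporter gene Slc2a2 (log2 −3.53 ± 0.58) and Reg1 (log2 −2.81 ± 0.30). With doublets kept, these 5 genes were not called, and the medians of both lists were −0.34 and −0.32. The goblet genes Muc2 (log2 −3.27 ± 0.48) and Zg16 (log2 −4.28 ± 0.87) fell, Zg16 by 0.94 and not called without young replicate 1, and with doublets kept or at cluster resolution 2 neither was called. DESeq2 did not call Zg16 (adjusted p = 0.417). MHC class I processing genes were lower in 13 of 13 (median −0.69, camera adjusted p = 1.0e-05, adjusted p = 0.411 with an estimated correlation), and unfolded protein response genes had a median of −0.53 (camera adjusted p = 2.1e-05, adjusted p = 0.406 with an estimated correlation). Immediate early and dissociation stress genes were lower in 22 of 22 (median −1.33, camera adjusted p = 9.6e-06, adjusted p = 0.459 with an estimated correlation), but at −0.03 without young replicate 1 and not passing.

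Proliferation genes were higher in 23 of 26 in old enteroendocrine-like cells (median 0.72, camera adjusted p = 3.6e-08, adjusted p = 0.417 with an estimated correlation), and Top2a, a DNA topoisomerase of dividing cells, rose by 1.09 ± 0.23 (adjusted p = 0.0269, and 0.084 without old replicate 2). Top2a was not called in DESeq2 (adjusted p = 0.152) or with thinned sums (0.0776). A cluster led by Neurog3, for which transit-amplifying-like was the name with the next highest score, held 25.4% ± 4.38 of these cells in old and 17.3% ± 2.70 in young mice (exact permutation p = 0.333). Paneth markers were higher in 6 of 7 (median 2.33, camera adjusted p = 1.3e-05, adjusted p = 0.406 with an estimated correlation; 4.61 without young replicate 2). Lyz1 rose by 2.28 ± 0.34 and Itln1 by 2.33 ± 0.39. Of 10230 genes tested in enteroendocrine-like cells, 36 were higher and 118 lower. Library totals gave 72 and 107, with the median of all genes moved to 0.134, and DESeq2 gave 9 and 65. The count of 154 became 241 without old replicate 2 and 765 without young replicate 2. The class sum of young replicate 1 was the deepest, at 2497683 UMIs against 1124475 to 1232004 in the other libraries.

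In tuft-like cells, the chemosensory cells, Pcdh20, a protocadherin gene, fell from 43.2 ± 0.0382 to 1.95 ± 1.42 CPM (log2 −4.58 ± 0.46, adjusted p = 7.4e-04). Prickle2, a planar polarity gene, fell by 3.15 ± 0.46 on the log2 scale (adjusted p = 0.0123; by 4.91 without old replicate 1) and Hmgn3 by 2.84 ± 0.43 (adjusted p = 0.0137). Trib2 (log2 −3.56 ± 0.58) was called lower, but not without young replicate 1 (adjusted p = 0.181). Bst2, the interferon-induced protein tetherin, fell from 149 ± 1.03 to 74.5 ± 5.17 CPM (log2 −0.99 ± 0.17, adjusted p = 0.0229). Interferon response genes were lower in 25 of 27 (median −0.37, camera adjusted p = 5.4e-05) and MHC class I processing genes in 14 of 14 (median −0.49, camera adjusted p = 3.8e-06), each with an adjusted p of 0.687 with an estimated correlation. The interferon median was −0.57 with doublets kept. DESeq2 did not call Hmgn3, Trib2 or Bst2, and with thinned sums they were not called either (adjusted p = 0.054, 0.172 and 0.088).

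Dmbt1, a secreted scavenger receptor, rose in tuft-like cells from 24.8 ± 5.77 to 66.9 ± 1.40 CPM (log2 1.51 ± 0.24, adjusted p = 0.016), a gene that was not called in DESeq2 or with thinned sums (adjusted p = 0.0658). Paneth markers were higher in 5 of 5 (median 3.50, 2.10 with doublets kept, camera adjusted p = 6.2e-08, adjusted p = 0.687 with an estimated correlation), with Itln1 at 3.50 ± 0.58, not called without old replicate 1 (log2 2.19, adjusted p = 0.471) or with doublets kept (log2 1.17, adjusted p = 0.231). Ddx3y, a Y-linked helicase gene, was called 4.53 ± 0.63 higher, not called without old replicate 1 (log2 3.01, adjusted p = 0.122) or with thinned sums (0.0687), and old replicate 1 is the library with other Y-linked transcripts. Proliferation genes were higher in 12 of 12 (median 0.70, camera adjusted p = 8.7e-05, adjusted p = 0.687 with an estimated correlation). That median was 0.34 and did not pass without old replicate 2, and was 1.61 without old replicate 1 and 1.32 without young replicate 2. Of 8770 genes, 27 were higher and 13 lower, and DESeq2 gave 18 and 6. The balance turned without old replicate 2 (41 higher, 64 lower) and without young replicate 2 (251 higher, 280 lower). The count of 40 became 120, 105, 94 and 531 without old replicate 1, old replicate 2, young replicate 1 and young replicate 2, and young replicate 1 held 476 of the tuft-like cells against 100 to 182 in the others.

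Paneth markers passed camera as higher in old mice in 6 of the 7 comparisons, all but that of goblet-like cells. MHC class I processing genes and immediate early and dissociation stress genes passed as lower in all 7 with all 4 libraries. In tuft-like cells the latter had a median of −0.32 (camera adjusted p = 0.00537, adjusted p = 0.687 with an estimated correlation). That list did not pass there without old replicate 1 (−0.30) or young replicate 1 (−0.24). The stress list leaned on young replicate 1 in other comparisons too. Without that library its median was −0.52 over all epithelial cells (−1.05 with all libraries), −0.18 in stem-like cells (−0.44) and −0.03 in enteroendocrine-like cells (−1.33). The 5 classes of stem-like, transit-amplifying-like, enterocyte-like, enteroendocrine-like and tuft-like cells held 2.73 to 6.36 UMIs of Paneth markers per cell in old libraries and 0.132 to 0.909 in young libraries. Genes of p53 and senescence had medians of −0.14 over all epithelial cells (camera adjusted p = 0.0649), −0.16 in stem-like cells (0.073) and −0.13 in enterocyte-like cells (0.0916), none of which passed. Over all epithelial cells, nuclear OXPHOS genes (median −0.02, camera adjusted p = 0.612), Wnt targets (median 0.15, 0.0863) and lipid uptake genes (median −0.23, 0.079) did not pass either. Ribosomal protein genes passed with a small median (0.18, camera adjusted p = 1.9e-04, adjusted p = 0.686 with an estimated correlation). The other 2 ways to split the 4 libraries into pairs gave 0 calls in edgeR in each class, with 4 in tuft-like cells for old replicate 1 with young replicate 1 as the exception. At an unadjusted p under 0.05 they gave 146 to 486 genes. Each of these splits puts an old and a young mouse in the same group, so that any age difference adds to the spread within groups. Few calls were therefore likely in advance, and these counts are no reference for the age calls.

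**Figure D4:**
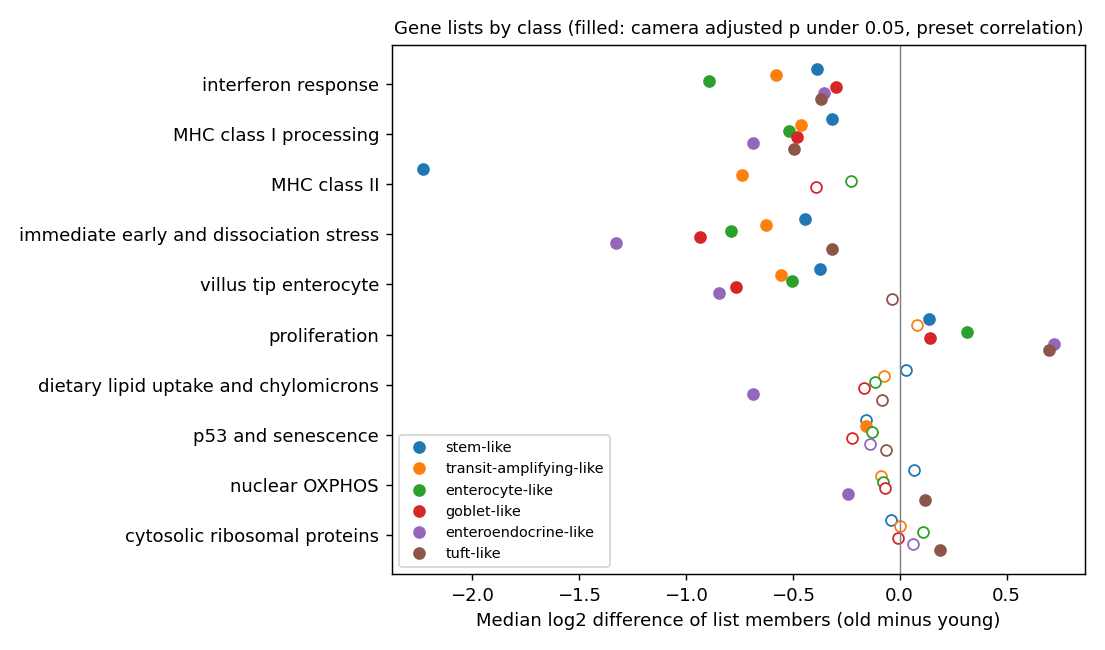
Median log2 difference (old minus young) of the members of 10 gene lists in each of the 6 classes, with filled points for a camera adjusted p under 0.05 at the preset correlation. Interferon response genes lay at −0.89 in enterocyte-like and at −0.58 in transit-amplifying-like cells.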

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

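Among the tests in this part, those of processed copies in the 12 genes and of the interferon list in single classes without young replicate 2 and over the classes without old replicate 1 were chosen only after the result was seen.

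T-cell-like cells were 0.652% of the cells kept in old replicate 1 (95% interval 0.503 to 0.832), a signal in cells left out of the comparisons and in a sort that selects against CD45, against 0, 0.0847 and 0.262% in old replicate 2, young replicate 1 and young replicate 2.

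A set of 12 genes, among them Ctla4, Wdr89, Rps27rt, Nlrp4e and Rpl9-ps6, was called higher in old libraries in at least 4 of the 6 classes. Of these genes, 33.3% hold or are a processed pseudogene on their own strand, against a mean of 2.13% and a 95th percentile of 8.33% in random sets matched on expression and length. Rpl9-ps6 and Rps27rt are annotated as protein-coding genes without such a copy and were not counted. Over all other genes of stem-like cells, those with such a copy lay 0.0323 above those with a copy on the opposite strand alone (medians, permutation p = 0.044), so that reads of abundant genes placed on copies may account for part of the pattern. Larger UMI totals of the old class sums are argued against, because with class sums thinned to the lowest total 80.0% of the calls (44 of 55) were kept. In goblet-like cells the old sums were in fact the smaller (5057250 and 5115855 against 6045657 and 5522354 UMIs). Thinning leaves the proportions of genes unchanged, so that it cannot test depth per cell or the placement of reads. Why such placement would follow age was not tested, and age itself stays open.

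Paneth transcripts were higher in old libraries in 5 other classes, and old libraries held more Paneth-like cells. If free RNA of Paneth cells were the source, the marker genes would keep a single ratio to their level in Paneth-like cells. The SD of that log2 ratio, over 4 to 10 markers in each class and old library, had a median of 0.675 (range 0.126 to 0.864), between the 0.5 that free RNA was set to need and the bound of 1 that would have argued against it. In these classes of the old libraries the markers lay at a median of 0.0523 to 0.251% of their level in Paneth-like cells. They summed to 277 to 399 CPM in stem-like, transit-amplifying-like and enterocyte-like cells, and to 662 to 1079 CPM in enteroendocrine-like and tuft-like cells. Enteroendocrine-like and tuft-like cells hold fewer UMIs per cell, and per cell the markers were closer, at 2.73 to 3.44 UMIs against 3.16 to 6.36 UMIs. Counting error of markers with few UMIs also adds to the SD, so that an SD above the lower bound does not speak against free RNA. By the bounds set, free RNA and expression within these classes cannot be told apart here, and age stays open as an untested explanation.

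Interferon response and MHC class I processing genes were lower in old libraries, and MHC class II genes were lower in stem-like cells, but in enterocyte-like cells Cd74 was not called. This does not show a difference between these classes, because no gene passed the direct test of stem-like against enterocyte-like cells. A young library standing apart is a candidate explanation in 3 of the 6 classes, because without young replicate 2 the interferon median was −0.382 in enterocyte-like cells (−0.892 with all libraries), −0.108 in stem-like cells (−0.387) and 0.0661 in goblet-like cells (−0.299). It is argued against as the whole cause, because the other 3 classes kept their median without that library. That was −0.608 in transit-amplifying-like (−0.575 with all libraries), −0.420 in enteroendocrine-like (−0.355) and −0.441 in tuft-like cells (−0.369). The median over the 6 classes was −0.401 without that library and −0.378 with it, but it cannot show a loss in single classes. Sex alone is argued against for the interferon list, because without old replicate 1, which held the Y-linked transcripts, the median over the 6 classes was −0.412. Leukocytes among the stem-like cells are argued against for MHC class II, because 15 leukocyte genes together reached 11.7% of the level that Cd74 would require, although Cd79b alone exceeded its level (1.65 against 1.13 CPM). Age and differences in handling stay open, and handling was not tested.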

How the results depend on the processing

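In this part, leaving out genes with processed copies, single enteroendocrine-like clusters and lifting the mitochondrial limit were tests chosen only after the results were seen. Counts of called genes depended on the setting, and the cause was not tested except where fewer genes, cells or libraries entered. Without a low-count filter the counts were 7 (epithelial cells together, 0 otherwise), 404 (stem-like, 39), 480 (transit-amplifying-like, 63), 0 (enterocyte-like, 1), 0 (goblet-like, 38), 483 (enteroendocrine-like, 154) and 247 (tuft-like, 40). DESeq2 gave, in that order, 654, 63, 155, 111, 66, 74 and 24. Library totals gave 78 in stem-like and 17 in transit-amplifying-like cells, and RLE 2 in enterocyte-like cells. A mitochondrial limit of 10% gave 6 in epithelial cells together, 38 in transit-amplifying-like and 14 in enterocyte-like cells. With doublets kept there were 4 in enterocyte-like, 92 in enteroendocrine-like and 361 in tuft-like cells, and at cluster resolution 2 there were 24 in transit-amplifying-like and 0 in enterocyte-like cells. Thinned sums gave 70 in stem-like, 100 in enteroendocrine-like and 14 in tuft-like cells. Without genes holding a processed copy there were 25 in stem-like, 25 in transit-amplifying-like and 20 in goblet-like cells. The enteroendocrine-like clusters led by Chga, Gip and Neurog3 alone gave 79, 68 and 17.

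Leaving out a library leaves an age with 1 mouse, assumed to vary like the other age. The ranges were 227 to 3310 (epithelial cells together), 57 to 847 (stem-like), 91 to 2218 (transit-amplifying-like), 90 to 406 (enterocyte-like), 47 to 380 (goblet-like), 201 to 765 (enteroendocrine-like), 94 to 531 (tuft-like) and 20 to 394 (interaction). Share differences then ranged, in points, from −0.445 to 2.66 (stem-like), 10.2 to 12.3 (transit-amplifying-like), −11.0 to 2.18 (enterocyte-like), −2.96 to −2.02 (goblet-like), 0.662 to 0.858 (Paneth-like), −3.22 to −0.137 (enteroendocrine-like) and −8.64 to −0.341 (tuft-like). The stem-like share reversed without old replicate 1 (−0.169) and young replicate 2 (−0.445), and the enterocyte-like share without young replicate 2 (2.18) and with libraries clustered alone (0.29). Enterocyte markers over all epithelial cells reversed without young replicate 2 (0.13, and −0.85 without young replicate 1), and Fabp6 in enteroendocrine-like cells with doublets kept (2.67). Of 1273 values of the 94 named and called results, 1101 kept direction and threshold and 171 lost the threshold. Of 1186 values of the 81 lists, 936 kept both and 249 lost it. A gene left out of a setting gave no value there. Without genes under 5% of their highest class, 61 of the 94 results gave a value, and these kept both. Left out there were the named Paneth markers, Ptpn6, Ang4 and Cck in goblet-like cells, and Isg15 in transit-amplifying-like cells. Muc2, Zg16, Slc2a2 and Reg1 in enteroendocrine-like cells were also among those left out. No paired analysis was possible because the replicate numbers only follow the order of the samples.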

Other observations

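Paneth-like sums were tested although young replicates held 7 and 26 such cells, a test chosen only after the data were seen. Mptx2, a pentraxin of Paneth cells, fell from 2962 ± 1251 to 313 ± 148 CPM in old mice (SD, n = 2 each; log2 −3.24 ± 0.49 SE, edgeR adjusted p = 0.0159). Defa21 (log2 3.07 ± 0.47) and Defa22 (log2 2.96 ± 0.46) were called higher, and they belong to a family of near-identical genes. No other of the 5053 genes tested was called, with 203 at an unadjusted p under 0.05.

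Haemoglobin transcripts stood out in old replicate 2. Hbb-bs was at 24.8 CPM in its epithelial cells, against 0.858 CPM in old replicate 1 and 0.117 and 1.45 CPM in young replicates 1 and 2. Hba-a1 was at 4.24 CPM, against 0.202, 0 and 0.246 CPM. Myeloid-like cells numbered 14, 2, 0 and 21 in old replicates 1 and 2 and young replicates 1 and 2. A cluster without a name, with few UMIs per cell and led by Ada, Sprr2a3 and S100g, held 0.438 and 0.365% of the cells kept in the old libraries and 1.02 and 1.15% in the young libraries. Its highest score was for enterocyte-like cells (2.25), and it stayed unnamed by the rule on UMIs per cell. These cells are therefore not part of the enterocyte-like shares.

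Over all barcodes, old replicate 2 held 6.26 UMIs of Ddx3y per 100 UMIs of Ddx3x although it held 1 UMI of the other Y-linked genes, against 40.5 in old replicate 1 and 1.54 and 1.63 in the young libraries. Ddx3y holds the processed pseudogene Gm4017 on its own strand.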
